A study of Homo sapiens with 2 samples.

How the data were processed

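RNA immunoprecipitation followed by sequencing (RIP-seq) was carried out on 1 cytoplasmic lysate preparation of DU145 cells, an established human prostate cancer cell line. Per the labels' protocols, the lysate was pre-cleared on beads and divided between a rabbit antibody against eIF4A1 and control rabbit IgG, and the recovered RNA was made into strand-marking, random-primed libraries. The series used here has 2 samples, 1 eIF4A1 immunoprecipitate and 1 IgG immunoprecipitate, with 1 library per group, and both carry the set number 2 in their titles. Groups were taken from the antibody label. With 1 library per group no difference had a replicate check, and no p-value was computed across genes.

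Per the submitters' processing notes, STAR, Salmon, Picard, DESeq2, BWA, MACS2 and ChIPseeker were used, without versions, settings or order, and hg19, GRCh38 and hg38 were named as builds. Of these, the peak track has the layout of MACS2 output and the annotated table the columns of ChIPseeker output. The peak track, filed under the IgG sample, gives each peak's interval, a score, the fold over control as a linear ratio, and the −log10 p and −log10 q values, per the file headers and the narrowPeak column order. Its peaks are all named after the eIF4A1 library, so it was read as the eIF4A1 peak set called over a control, and not as a list of IgG regions. Which library served as the control is not given in the sources used here. The design pairs eIF4A1 with IgG, but the protocol also set aside an input, so reads behind the background are called control reads. The score deposited by the authors equals the whole part of 10 times −log10 q in all 1920 peaks. The annotated table, deposited for the eIF4A1 sample, lists 1-base summits, −log10 q, an annotation class and the nearest gene. Its 2051 rows hold 1919 peaks because some gene IDs are listed under several names. All 1919 peaks have the same summit and −log10 q in both files, and 1 peak is in the track only. Peak names run from 18 to 1937 and carry the word filtered, and what the filter was is not given in the sources used here. The planned overlap of eIF4A1 peaks with IgG regions therefore reduced to this identity check. No peak lies on the mitochondrial chromosome, and 0 symbols of the list of mitochondrially encoded genes matched the RefSeq table, so that list was not examined.

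Coordinates are those of hg38 (GRCh38), 1-based: of 1913 peaks on placed chromosomes with a gene in the RefSeq table (GRCh38.p14), the authors' transcript overlapped the RefSeq span of the same gene ID in 1901. Gene symbols were taken from RefSeq through the deposited gene ID, which was found for 1918 peaks. The deposited tables give no strand for a peak, so overlapping and antisense genes cannot be told apart.

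Library totals were not given in the sources used here, and the depth of each library was not estimated. The depth of each peak was recovered from the deposited fold and −log10 p values. MACS2 gives a fold of (reads + 1)/(background + 1) and the Poisson probability of more than the observed reads, which leaves 2 unknowns and 2 equations. Solved without forcing a whole number, all 1920 peaks gave a read number within 0.01 of a whole one (largest distance 0.00046), against 17.4% after p was shuffled among the peaks. In 16 peaks a second whole solution lay within the same tolerance, and the nearest was used. On 500 simulated peaks the read number was recovered in 100%. These reads are those stacked at the summit as the caller counted them. This derivation rests on that formula, since the tables hold no read counts. Whether duplicates had been removed is not given in the sources used here, and binomial intervals (exact Clopper-Pearson, 95%) cover counting error only.

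A gene was counted as having a peak when the authors' table named it for a peak not called intergenic. The text names the 20 genes with the highest fold, the genes with most peaks (the 10th place was shared, so 13 genes with 4 or more peaks are named), up to 4 members of each gene list by fold, and EIF4A1. Other genes named (ABL1, LINC03061, FTX, ENO1, RNA45SN3 and those of the lipid list) were chosen after their values were seen. Some genes that the rule names are not reported here. The naming rule and 17 gene lists were fixed before the data were examined: eIF4F subunits and partners, other initiation factors, elongation factors, cytosolic ribosomal proteins, growth and survival genes, replication-dependent histones, mitochondrially encoded genes, nuclear long noncoding RNAs, snoRNA host and cytoplasmic long noncoding RNAs, abundant small noncoding RNAs, abundant housekeeping genes, epithelial and mesenchymal markers, androgen receptor and luminal prostate markers, endoplasmic reticulum (ER) stress and integrated stress response, glycolysis and hypoxia, chaperonin and proteasome, and blood and stromal markers. Each list's share was set beside that of all 20056 RefSeq protein-coding genes. Lists of protein-coding genes were also set beside 10000 random lists drawn from the same 10 bins of gene-body length. No random lists were drawn for the lists of noncoding RNAs, which have only the protein-coding share beside them. The median of the best folds of each list's members was placed among 10000 random sets of as many genes with a peak. Expression levels were not analysed here, so these backgrounds include genes that DU145 cells may not express. The random-list calculation was run on simulated data, where no draw reached a planted list of 20 hits in 40, and 2957 of 10000 reached an unplanted list. Simulated hits were independent of gene length, so the length matching was not tested. The planted contrast was large, so this check does not bear on small margins. Alternatives were a −log10 q of at least 5, a fold of at least 5, merging of peaks within 100 bases, share of bases, RefSeq gene bodies, exon and UTR peaks only and removal of contigs. The exon and UTR setting kept the authors' exon and UTR classes, with exon peaks only where the exon belonged to the named gene. It left out every promoter-class peak, wherever in the gene that peak lay. Added after the data were seen were a minimum of 5 reads, a background of at least 1 control read and gene bodies for the lists. Base composition and a recomputed exon and UTR annotation need a genome and transcript models that were not used here. Python 3.11.15, SciPy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.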

Results

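RNA bound by eIF4A1 was profiled in DU145 cells to identify the transcripts that associate with this protein. eIF4A1 is the DEAD-box RNA helicase of the eIF4F cap-binding complex and unwinds structure in mRNA leaders during translation initiation. The lysate was divided between an eIF4A1 immunoprecipitation and a control IgG immunoprecipitation, and each was sequenced as 1 library. The deposited result is a set of 1920 peaks called in the eIF4A1 library, of which 1919 carry an annotation. Each fold below is the authors' value for that peak over control, and no fold has a replicate error because there was 1 library per group. The library totals were not given, so depth is stated per peak, as reads recovered from the deposited values.

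The eIF4A1 peaks were assigned to 1539 genes, of which 1370 were protein-coding (6.83% of the 20056 protein-coding genes in RefSeq), 97 were long noncoding RNAs and 37 were microRNA genes. FASN, which encodes fatty acid synthase, carried both the highest fold and the largest number of peaks. Most genes had little support: 1327 had 1 peak, 163 had 2 peaks and 49 had 3 or more.

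Among peaks outside intergenic sequence, the highest fold was 13.3 at FASN (chromosome 17, 82080380 to 82080453, −log10 q = 17.1), where 14 eIF4A1 reads stood at the summit. CIC, encoding the transcriptional repressor capicua, followed with a fold of 12.3 and 12 reads (chromosome 19, 42294963 to 42295022). The long noncoding RNA LOC105371789, whose peak also lies inside HDAC5, had a fold of 10.8. BICDL1, which encodes a dynein adaptor, and KIF3C, a kinesin gene, both had a fold of 10.6, and FBRSL1 had 10.3. Each of the last 4 peaks rested on 10 reads. A fold of 10 or more was found at 8 peaks in all.

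The next genes by fold included SOD2 (8.90), the gene of mitochondrial superoxide dismutase. ACLY, encoding ATP citrate lyase, had a fold of 8.51 with 15 reads at its summit. EIF1, encoding the initiation factor that acts in start-codon selection, had 8.27 (chromosome 17, 41688949 to 41689059). ARRDC1 had 8.41, the kinase gene MAPKAPK2 and DLGAP4 each had 8.14, and PRKCSH, the zinc transporter gene SLC39A7 and the kinase gene TAOK2 each had 8.01. The authors' assignment of 3 further genes in this group did not match the RefSeq gene at the summit. The peak listed under QRFP (8.35) lies in ABL1, the peak listed under MYO16-AS1 (8.51) lies in the long noncoding RNA LINC03061, and the peak listed by gene ID under both RGPD1 and RGPD2 (7.86) lies in RGPD2, of a family of near-identical copies, and is uncertain.

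FASN carried 23 peaks, 1.20% of all peaks, and all 23 summits lie inside its RefSeq span (chromosome 17, 82078338 to 82098236). They extended over most of the gene, with folds from 3.52 to 13.3 (median 6.91) and 3 to 18 reads at the summit. The recovered background at these peaks had a median of 0.144, against 0.0176 over all peaks, and reached 4.40 at the peak of 18 reads. The control therefore also held more reads at FASN than at most peaks. BCAM, encoding a laminin-binding surface glycoprotein, and CIC each had 7 peaks. PITPNM1 had 6, of which 5 lie inside it, and CLIP2 and the transcriptional repressor gene BCL6 each had 5. The U1 small nuclear RNA gene RNVU1-18 was listed with 5, only 1 of them inside its RefSeq span, and its many near-identical copies make that assignment uncertain. JUP (plakoglobin), ACACA (acetyl-CoA carboxylase), DHCR7 (the last enzyme of one branch of cholesterol synthesis) and APLP2 each had 4 peaks inside the gene. The 4 peaks listed under FGF11 lie outside it, and of the 4 listed under RNA5-8SN4, a 5.8S ribosomal RNA gene, 2 lie on the contig of that gene, 1 on another contig and 1 on chromosome 21 in RNA45SN3, so that assignment is uncertain.

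**Figure D1:**
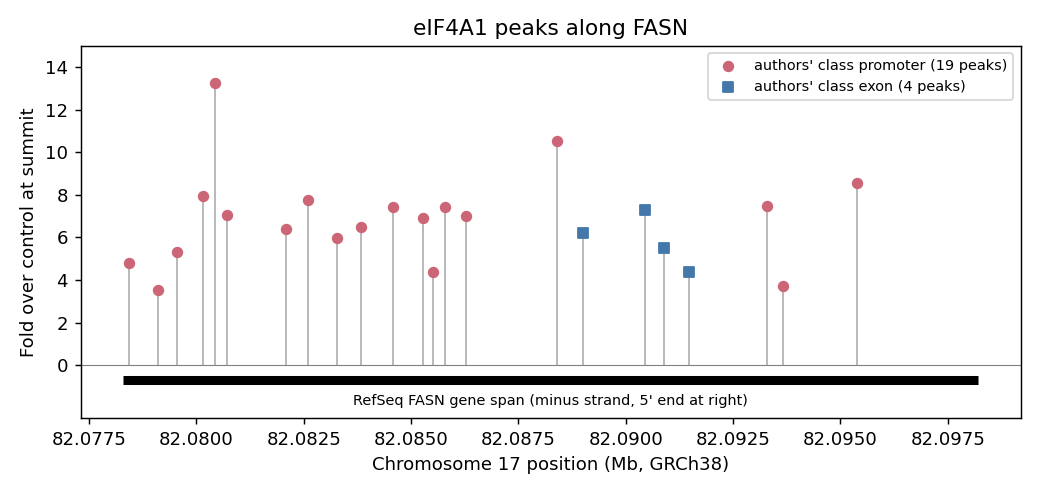
Authors' fold over control (y axis) of each of the 23 eIF4A1 peaks at its summit position on chromosome 17 (x axis, megabases, GRCh38). Circles are the 19 peaks in the authors' promoter class, squares the 4 in the exon class, and the black bar is the RefSeq span of FASN, along most of which peaks are spread.

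Read support at single peaks was low. Of the 1920 peaks, 371 rested on 2 reads and 715 on 3, together 56.6% (95% interval 54.3 to 58.8). At least 5 reads were found at 513 peaks (26.7%, interval 24.8 to 28.8) and at least 10 at 88 peaks (4.58%, interval 3.69 to 5.62). The fold therefore had a narrow range, with a median of 3.99 and quartiles of 3.90 and 4.95, and peaks were short, with a median of 27 bases and 775 peaks of exactly 20 bases. A difference of 1 read between peaks is within counting error, so neighbouring ranks by fold were not distinguishable at this depth.

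**Figure D2:**
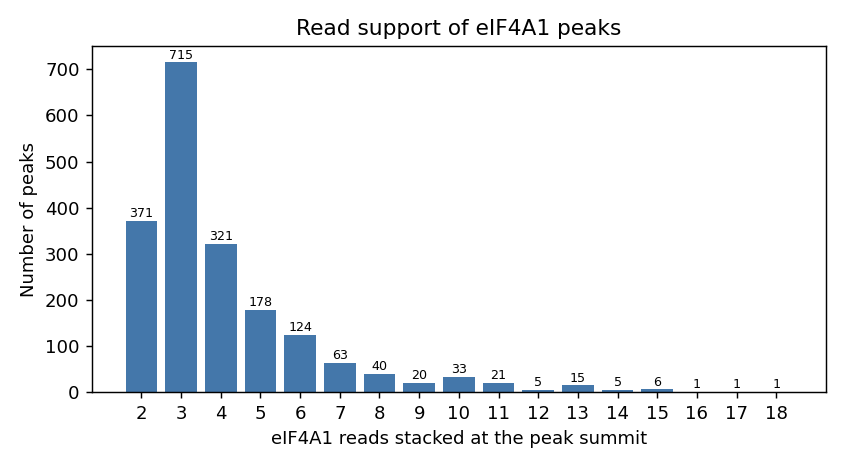
Number of peaks (y axis) for each number of eIF4A1 reads stacked at the summit (x axis), recovered from the deposited fold and p. The 2 commonest values are 3 reads (715 peaks) and 2 reads (371 peaks), and the highest is 18.

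In the authors' annotation, 1099 of 1919 peaks (57.3%, interval 55.0 to 59.5) lay within 3 kb of a transcript start and were classed as promoter. A further 384 were in exons, 244 (12.7%) in 3' UTRs, 95 (4.95%) in introns, 75 (3.91%) in distal intergenic sequence, 15 (0.782%) in 5' UTRs and 7 just downstream of genes. Each peak has 1 class, so a peak in a 5' UTR within 3 kb of a transcript start can be classed as promoter. The 5' UTR share therefore may not count every peak in an mRNA leader. The intron share was lower under each stricter setting, at 2.77% with a −log10 q of at least 5, 1.17% with at least 5 reads and 0.676% with a background of at least 1 control read, and 2.84% by bases. The intergenic share was 2.97%, 1.36% and 3.38% under the 3 stricter settings in that order and 3.13% by bases, and 5.47% of peaks lay outside every RefSeq gene. Against the 5' end of the whole RefSeq gene, 454 of the 1099 promoter-class peaks (41.3%, interval 38.4 to 44.3) lay within 3 kb, and 623 lay more than 3 kb downstream of it. In FASN, 19 of 23 peaks were in the promoter class and 1 of these 19 lay within 3 kb of the 5' end of the gene.

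The gene that the authors' table names was not always the gene that holds the peak. Of 1844 peaks not called intergenic, 1484 (80.5%) lay inside the named gene, 312 lay only in another RefSeq gene and 48 in none. Among 244 peaks in the 3' UTR class, 72 lay only in another gene. Conversely, 18 of the 75 peaks called intergenic lay inside a RefSeq gene. For ABL1, the tyrosine kinase gene, both of its peaks (folds of 8.35 and 6.80) were listed under QRFP.

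Among genes of the translation machinery, EIF4A1 itself had 0 peaks by either assignment. Of 15 eIF4F subunits and partners, 2 had a peak: EIF4A3, the helicase of the exon junction complex (fold 5.77, 5 reads), and EIF4G3, a scaffold subunit (4.91, 4 reads). Of 35 other initiation factors, 3 had a peak, namely EIF1, EIF3B (5.03) and DDX3X (4.67). Of 10 elongation factors, 2 were listed, EEF2 (5.41) and EEF1D (3.91), the latter with its summit outside the gene. Of 79 cytosolic ribosomal protein genes, 4 had a peak (5.06%): RPL23A (4.60), RPS4X (4.25), RPL37A (3.99) and RPS24 (3.99), each on 3 or 4 reads and RPL37A with its summit outside the gene. Counts as high or higher came up in 2919, 4411, 1394 and 5016 of 10000 length-matched random lists for these 4 lists in turn. In the same order, the counts were 2, 1, 0 and 2 at a −log10 q of at least 5, and 1, 0, 0 and 2 with exon and UTR peaks alone. The exon and UTR setting leaves out every promoter-class peak, that of EIF1 included, so its counts do not show a lack of exonic peaks. With settings chosen after the data were seen they were 1, 2, 1 and 0 with at least 5 reads, and 0, 1, 0 and 0 with a background of at least 1 control read.

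ER stress and integrated stress response genes had a peak in 4 of 20, a count that 337 of 10000 random lists reached. They were HSPA5, the ER chaperone BiP (7.59, 9 reads), ATF3 (5.51), ATF6 (4.67) and ERN1 (3.92). Growth and survival genes had a peak in 4 of 40, reached by 3336 random lists. Among them were STAT3 (5.85, 10 reads), a cytokine-signalling transcription factor, HIF1A (5.32, 9 reads), the hypoxia-inducible factor, and CXCR4 (4.35), whose summit lies outside the gene. Glycolysis and hypoxia genes had a peak in 3 of 20, PGAM1 (5.73), HIF1A and the pyruvate kinase gene PKM (5.32), reached by 1470 random lists. The counts for ER stress, growth and glycolysis depended on the peak definition, and the settings differed in direction. At a −log10 q of at least 5 they were 1, 0 and 1, and with exon and UTR peaks alone, without the promoter class, 3, 1 and 1. With a minimum of 5 reads, a setting chosen after the data were seen, they were 2, 4 and 3, reached by 536, 92 and 72 random lists, and the other protein-coding fixed lists were reached by 1679 or more. With a background of at least 1 control read, also chosen after the data were seen, they were 1, 3 and 2, reached by 1019, 8 and 43, and the others by 1290 or more. The growth counts of 4 and 3 include CXCR4, and HIF1A stands in the growth and the glycolysis lists. These counts describe 1 pair of libraries, and no p-value is attached to them.

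**Figure D3:**
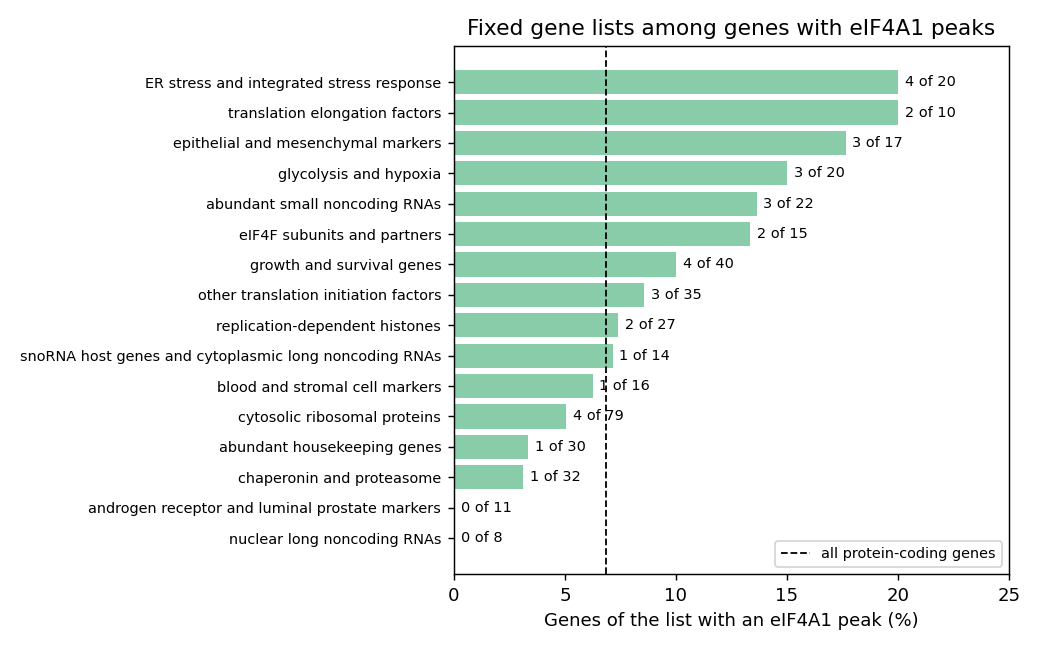
Percentage of the genes of each fixed list with an eIF4A1 peak (x axis), with the count beside each bar and the dashed line at the 6.83% of all protein-coding genes. The list of mitochondrially encoded genes is left out because 0 of its symbols matched the RefSeq table.

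The remaining lists had from 0 to 3 genes named each, a share of up to 17.6%. PKM was the only one of 30 housekeeping genes named (7853 random lists reached that count). By gene body ENO1 is added, with an 8-read peak (4.79) listed under MIR6728, which makes 2 of 30 and, for glycolysis and hypoxia, 4 of 20. PSMB5 (2.95, 2 reads, summit outside the gene) was the only one of 32 chaperonin and proteasome genes (8853). Replication-dependent histone genes were named in 2 of 27, H4C2 (4.88) and H1-1 (3.98), both with summits outside the gene (1555). Abundant small noncoding RNAs had 3 of 22: RN7SL1, the signal recognition particle RNA (3.98, 17 reads), RNU2-1 (3.95, summit outside the gene) and RNU4-1 (3.93). Of 14 snoRNA host and cytoplasmic long noncoding RNAs, EPB41L4A-AS1 (2.95) had a peak, and of 8 nuclear long noncoding RNAs 0 were named, although 1 peak listed under MIR421 lies in FTX. Epithelial and mesenchymal markers had 3 of 17, ANXA2 (4.86), FN1 (3.94) and CD44 (3.92), a count reached by 937 random lists. Their count was 0 at a −log10 q of at least 5, 2 with exon and UTR peaks alone and 1 with at least 5 reads. The androgen receptor and luminal prostate markers had 0 of 11, as did 4493 of 10000 random lists. Of 16 blood and stromal markers, VWF had 1 intronic peak (2.99, 2 reads), a count reached by 6183.

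Among lists with 2 or more members with a peak, the median best fold of these members stood at the 92.8th percentile of random sets for growth and survival genes, at the 88.1st for glycolysis and hypoxia, at the 87.0th for ER stress, at the 86.1st for other initiation factors and at the 83.9th for eIF4F. It stood at the 62.1st for elongation factors, the 53.3rd for histones, the 44.1st for ribosomal proteins, the 37.4th for small noncoding RNAs and the 36.7th for epithelial and mesenchymal markers. These medians rest on 2 to 4 genes each. The housekeeping, blood and stromal, snoRNA host, and chaperonin and proteasome lists had 1 such gene each, so no percentile is given for them.

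Peaks were unevenly divided among chromosomes. Chromosome 17 held 14.9 peaks per 100 protein-coding genes (174 peaks) and chromosome 19 held 14.3 (208 peaks), against 5.84 on chromosome 4 (45 peaks) and 4.13 on the X chromosome (35 peaks). FASN accounted for 23 of the chromosome 17 peaks.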

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

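All tests in this part were chosen after the result was seen. The long noncoding RNA LINC03061 (chromosome 13, 109265487 to 109271075) held 6 peaks. Of these, 4 are in data outside the gene counts, since the authors' table calls them distal intergenic, and the other 2, in the exon class, are counted under MYO16-AS1. Its best fold was 11.2, with 13 reads at the summit, and its 6 summits carried 8 to 15 reads each. The 1 peak present only in the track lies on an unlocalized contig of chromosome 1 and had a fold of 3.93 on 3 reads.

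Most peaks fell in the promoter class although RNA was measured. Transcript starts inside genes may account for this, since 41.3% of promoter-class peaks lay within 3 kb of the 5' end of the RefSeq gene, which is under 50%. The 454 peaks near a gene's 5' end are open to a biological reading, which was not tested.

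Most peaks rested on 2 or 3 reads. Such stacks passed the threshold only over a low background, since no peak under 8 reads was kept with a background of at least 1 control read. The recovered background was under the value of 1 control read in 94.1% of peaks. Whether it was low because the control was sparsely sequenced or because it held little RNA there stays open. Setting the background to at least 1 control read kept 7.71% of peaks, which are the 148 with at least 8 reads. This setting is therefore a minimum of reads and does not show why the background was low. Whether the peaks on few reads reflect weak binding or sampling of expressed RNA was not tested, because no second pair of libraries was analysed here.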

How the results depend on the processing

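The peak and gene counts depended on how strictly a peak was defined. From 1920 peaks, 505 had a −log10 q of at least 5, 432 a fold of at least 5, 513 at least 5 reads and 148 a p that held with a background of at least 1 control read, which are the peaks with at least 8 reads. The −log10 q also depends on the background, so a higher value does not mean more reads. The RPS24 peak passed with 3 reads (5.49), while the FASN peak of 18 reads (2.08) did not. From 1539 genes, the counts were 459, 424 and 114 for the q, read and background settings. The promoter share of 57.3% was 60.0% at the stricter q, 61.1% by bases, 65.5% with at least 5 reads and 70.9% with the control background. Of 388 distinct genes in the fixed lists 32 had a peak, against 7 at the stricter q, 10 with exon and UTR peaks alone, 14 with at least 5 reads and 7 with the control background. Promoter-class peaks are left out of the exon and UTR setting. Fewer peaks entered these settings by construction, except the share of bases, where the cause was not tested. The read and control background settings were chosen after the data were seen. Merging near peaks, RefSeq gene bodies, intergenic peaks and contigs moved the peak count, the gene count and the pooled list count by less than 1.5 times. Single lists did move by gene body. Histones went from 2 to 0, elongation factors from 2 to 1, and chaperonin and proteasome from 1 to 0. Housekeeping genes went from 1 to 2 and nuclear long noncoding RNAs from 0 to 1. Of the other values, 71 moved and 58 did not, where a share moved if it left its 95% interval and a count if it changed by over 1.5 times; FASN went from 23 peaks to 12 both at the stricter q and with the control background. Base composition and the recomputed exon classes were not run, nor were other overlaps with IgG regions, since both files hold the same peaks. No replicate could be left out with 1 library per group, and no paired analysis was possible because each antibody has 1 library.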

Other observations

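All tests in this part were chosen after the result was seen. Genes of fatty acid and sterol synthesis were frequent among the genes with peaks. A list of 43 such genes was written after 5 of them, FASN, ACLY, ACACA and DHCR7 included, had been noticed, and 20 of the 43 had a peak (46.5%), against 6.83% of protein-coding genes. Leaving out those 5 genes, 15 of 38 had a peak (39.5%). These 15 include MVD (fold 7.60), the decarboxylase of the mevalonate pathway, INSIG1 (5.70) and SCAP (2.99), which regulate SREBP processing, FDPS (5.43), SQLE (5.26), the squalene epoxidase gene, SCD (4.75), and SREBF2 (4.40, 15 reads), which encodes SREBP2. MSMO1, EBP, SC5D, TM7SF2, FDFT1, CYP51A1 and HSD17B7, further enzyme genes of the sterol route, had folds from 2.95 to 4.25 on 2 to 4 reads. By RefSeq gene bodies, 23 of the 43 held a peak, which added IDI1, STARD4 and LPIN1. With exon and UTR peaks alone, the counts were 11 of 43 and 6 of 38, and no random lists were drawn for that setting. It leaves out promoter-class peaks, such as those of MVD and SQLE.

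This pattern is a hypothesis found and tested on the same peaks, and its list was 1 beside the 17 fixed ones. Gene-body length is argued against, because the highest count among 10000 length-matched random lists was 10, below the 15 observed in the members not noticed beforehand. Gene bodies include introns, and transcript length without introns was not matched, so that length stays open. Peaks on few reads were first tested with a control background of at least 1 read, which equals a minimum of 8 reads. It kept 2 of these 38 genes (5.26%, against 0.504% of all protein-coding genes), which 193 random lists reached, the highest holding 4, and it decided nothing by itself. A count with at least 5 reads was added after that, and it gave 7 genes (18.4%, against 1.90%), which 0 random lists reached, the highest holding 6. These 7 genes had peaks of at least 5 reads, so the whole pattern does not rest on peaks of fewer reads, while the other 8 genes had only such peaks. Whether few reads account for the excess over random lists was not decided. The margin was 1 gene, at a cut chosen after the first had decided nothing. The random lists also include genes that DU145 cells may not express. At a −log10 q of at least 5 the excess was smaller, with 3 genes (7.89%, against 2.10%), a count that 528 random lists reached. That setting also drops peaks with many reads over a higher background, such as the 15-read peak of SREBF2 (2.91).

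High transcript abundance stays open. Housekeeping genes had a peak in 3.33% (1 of 30), against 6.83% of all protein-coding genes by the same assignment. By RefSeq gene bodies the housekeeping share was 6.67% (2 of 30), beside 1399 of all 20056 protein-coding genes. Abundant RNAs also give more control reads and are harder to call, and expression levels were not analysed here. At FASN the median background was 0.144, against 0.0176 over all peaks, so abundance stays open for that gene too. Preferential association of lipid-synthesis mRNAs with eIF4A1 may be a candidate explanation, which replicated libraries with expression levels could test.

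The recovered backgrounds also show how the control entered the peak calls. They fell on a grid: 314 peaks were at a common lowest value of 0.00298 reads, and all of the other 1606 were whole multiples, within 0.03 of a step, of the value of 1 control read counted over 10 kb for a fragment of 20 bases. A single control read at the summit was worth 0.880, and 521 peaks had the background of 1 control read within 1 kb (0.0176).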
